A study of Mus musculus with 6 samples.

How the data were processed

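Megakaryocytic-erythroid progenitors, bone marrow cells that give rise to megakaryocytes and red cells, were measured by RNA-seq in 6 mouse libraries, 3 from wild-type (WT) mice and 3 from Tmprss6 knockout (KO) mice. Each library was made from cells pooled from 3 mice, per the labels. Per the labels' protocols, marrow was depleted of lineage-positive cells and the pools were sorted as lineage-negative, cKit-positive, Sca-negative, Fc gamma receptor-negative, CD150-positive, CD105-negative and CD41-negative. RNA was amplified with SMART-Seq v4 and made into Nextera XT libraries, which do not mark the strand.

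The deposited values were read counts per Ensembl gene and library, whole numbers with no scaling. Per the submitters' processing notes, the authors used FastQC 0.11.5, STAR 2.5.3a and edgeR, and the notes name the builds GRCm38.p3 and GRCh38.p3. The read counter, its strand setting, its treatment of reads that map to several places and the annotation release are not given in the sources used here. Counts of paralogs, pseudogenes, overlapping genes and antisense genes are therefore uncertain. Coordinates are printed as the deposited table gives them. No row was without a gene name, and no other column of sample values was present in the table.

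Genes were filtered with filterByExpr of edgeR 4.0.16 at its defaults (a minimum count of 10 and a minimum total of 15), which kept 13453 of 52459 genes. Library sizes were scaled by TMM. Genotypes were compared with edgeR's quasi-likelihood test (glmQLFit, at this version's default, and glmQLFTest), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM, the counts scaled to a common library size, use TMM-scaled library sizes. Log2 values per library add a prior count of 2. Fold changes are KO over WT and SE is the standard error of the log2 fold change. R 4.3.3 was used.

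Groups were taken from the labels, and 35 gene lists were written before the data were examined, as were the tests and the rule for naming genes. Of these, 33 lists were tested as sets with camera of limma 3.58.1 at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 33 lists. Camera with an estimated correlation and fry were run beside it. The lists of sort-gate and sex-linked genes were not tested as sets. The balance of early erythroid over megakaryocyte genes was the difference of the mean log2 CPM of both lists per library, compared by an exact permutation test, whose smallest possible p with 3 against 3 libraries is 0.1. The rule named genes past the threshold with non-overlapping groups and at least 5 CPM in the higher group, predicted gene models left out. As 0 genes qualified, it named the 10 of smallest p that met the other conditions, which 352 genes did. It also named the sort-gate genes, Gata1, Gata2, Klf1, Fli1, Tmprss6 and up to 4 members of smallest p per list. Not every gene that the rule named is reported here.

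Both genotypes carry the replicate numbers 1, 2 and 3. Whether the numbers pair the libraries was decided from the deviations of log2 CPM from the group means: their correlation across genes was 0.53 for the libraries numbered 1, 0.16 for those numbered 2 and 0.63 for those numbered 3, each over 0.1. The pairing comes from the data, since the labels do not say what a number stands for. These values are not separate checks, because the deviations within a genotype cancel out. For number 2 the pairing is not shown by the log2 CPM themselves. Those of WT 2 correlated at 0.918 with KO 2, but at 0.958 with KO 1 and 0.954 with KO 3. A pair below means libraries of the same number. A fit with the replicate number as a block was planned as an alternative, and its values are given where they change a call. After the data were seen, the block fit was repeated on the pairs 1 and 3 alone, because KO replicate 2 carried transcripts of other blood cells. That fit leaves 1 residual degree of freedom and leans on a prior of 14.5 degrees of freedom. Other alternatives were DESeq2 1.42.0, limma voom with and without quality weights, other scalings, filters and thresholds, and leaving out each library.

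The fits were tested on simulated counts, with 199, 192 and 195 changed genes among those run for the 3 fits below. The fit of all 6 libraries recovered 1.0% of 2-fold and 23.2% of 4-fold changes, with 5 false calls among 13141 genes. The block fit recovered 24.0% and 66.7%, with 11 false calls among 13064 genes, and made 10 false calls on data without changes. The block fit of pairs 1 and 3 recovered 55.2% and 84.8%, with 12 false calls among 13152 genes, and 0 false calls on data without changes. In the simulation each gene varied independently, with dispersions taken from the same libraries and no shared change in cell content. Its false calls therefore say nothing on calls that come from other cells in the libraries. Total counts ran from 13402209 to 22986837 per library, so that 3 counts, taken as the floor, corresponded to 0.131 to 0.224 CPM. This floor covers counting error only, as the libraries carry no molecular identifiers.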

Results

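The libraries asked how loss of Tmprss6, a liver protease whose absence raises hepcidin and starves the body of iron, changes the transcriptome of marrow progenitors that can form platelet-producing megakaryocytes or red cells. There were 3 WT and 3 Tmprss6 KO libraries, each a pool of 3 mice. Total counts were 22986837, 14002110 and 13666585 in WT replicates 1 to 3 and 18105463, 15031367 and 13402209 in KO replicates 1 to 3. Between 17395 and 22028 genes had at least 1 count. Correlations of log2 CPM across genes, which are not independent replicates, were highest for KO 1 with WT 1 (0.979) and KO 3 with WT 3 (0.969). KO 2 with WT 2 had 0.918, pairs of WT libraries 0.919 to 0.968 and pairs of KO libraries 0.884 to 0.920.

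Tmprss6 (ENSMUSG00000016942, chromosome 15, 78439668 to 78468634) gave 5, 4 and 0 counts in WT replicates 1 to 3 and 0, 5 and 0 counts in KO replicates 1 to 3. The gene was near the floor of 3 counts in both groups and did not pass the filter, so the libraries' own Tmprss6 counts checked no label. Of the sort markers, Kit stood at 951 ± 634 CPM in WT and 713 ± 479 in KO (SD, n = 3), and Slamf1 (CD150), Eng (CD105) and Itga2b (CD41) had log2 fold changes of 0.093, -0.11 and -0.0030, none past the threshold. Kit was lower in KO in 3 of 3 pairs, with a log2 fold change of -0.41 in the block fit (edgeR adjusted p = 0.995; 0.086 to 1.00 over the alternatives). Ly6a, the Sca-1 gene, was at 1.35 to 2.69 CPM in WT and 3.60 to 13.9 in KO (log2 fold change 1.77, edgeR adjusted p = 1.00). Fcgr3, a receptor gated out, was highest in KO replicate 2 at 182 CPM against 2.70 to 18.3 CPM in the other libraries, and Fcgr2b reached 28.8 CPM there. Replicate 3 of both genotypes came from female mice, with 351 and 175 Xist counts and at most 1 count of Ddx3y. Replicates 1 and 2 came from males, with at least 872 Ddx3y counts.

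KO replicate 2 carried transcripts of other blood cells at levels above the other 5 libraries; these example genes were chosen after their values were seen. The eosinophil granule gene Prg2 stood at 4637 CPM against at most 484 CPM elsewhere, and the neutrophil precursor genes Mpo and Elane at 1284 and 677 CPM against at most 170 and 81.8 CPM. The macrophage genes C1qb and Vcam1 reached 330 and 649 CPM against at most 30.8 and 56.6 CPM. The globin gene Hbb-bs and the red cell anion exchanger Slc4a1 reached 1627 and 678 CPM against at most 122 and 13.6 CPM. The median member of the basophil, mast cell and eosinophil list lay 4.51 log2 units above the mean of the other 5 libraries. The same median was 4.43 for the macrophage list, 2.63 for the lymphoid list and 2.17 for the globin and late erythroblast list. The sort excluded lineage-positive and Fc gamma receptor-positive cells. The pairs 1 and 3 leave this library out but hold transcripts of other cells too, with Prg2 at 484 CPM in WT replicate 1 and the plasma cell gene Jchain at 124 CPM in KO replicate 3.

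**Figure D1:**
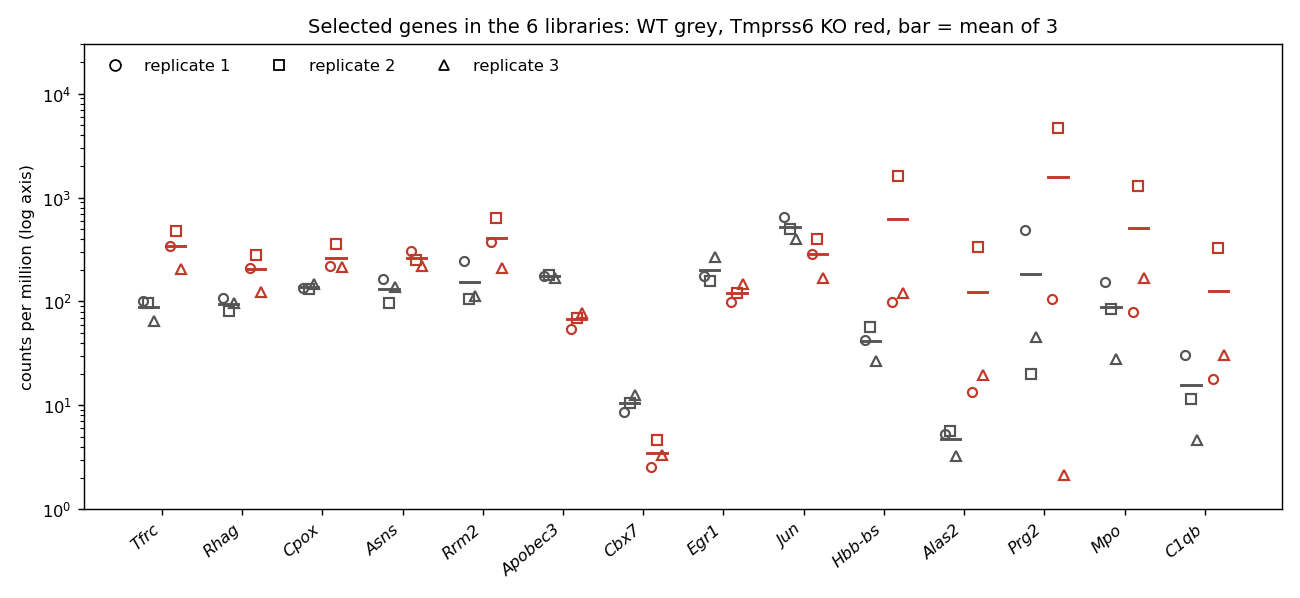
CPM (log axis) of 14 genes in the 6 libraries; grey symbols are WT, red symbols Tmprss6 KO, symbol shapes mark replicates 1 to 3 and bars are means of 3. Tfrc lies between 65.5 and 100 in WT and between 204 and 476 in KO, while Hbb-bs, Alas2, Prg2, Mpo and C1qb are highest in KO replicate 2.

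Tfrc, the transferrin receptor through which erythroid cells take up iron, was the gene with the clearest increase, although it did not pass edgeR's genome-wide threshold over all 6 libraries. Its level was 87.7 ± 19.3 CPM in WT and 341 ± 136 CPM in KO (SD, n = 3), a 3.89-fold difference (log2 fold change 1.96, SE 0.38, edgeR adjusted p = 1.00), and it was higher in 3 of 3 pairs. Across the genome, edgeR called 0 of 13453 genes, with a smallest adjusted p of 1.00. At an unadjusted p under 0.05 there were 234 genes, where chance gives 673. The block fit also called 0 genes, with 476 at an unadjusted p under 0.05 and a smallest adjusted p of 0.56, that of Tfrc. DESeq2 called 7 genes, 5 higher in KO (Igkv19-93, Tfrc, Trim10, Gda and Klri2) and 2 lower (Gml2 and Apobec3), with 510 at an unadjusted p under 0.05, and with the block it called 26 with 668. Igkv19-93, an immunoglobulin segment, had 162 and 3369 counts in KO replicates 2 and 3 and 0 in the other libraries. Limma voom called 0 genes with 97 at an unadjusted p under 0.05, and voom with quality weights 0 with 734. In 542 genes (4.03%) the KO and WT libraries did not overlap. Chance gives 10% for 3 against 3 libraries that can be exchanged, which libraries paired by number are not, so the shares cannot be compared.

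The other 9 genes of smallest p, none past edgeR's adjusted threshold, included 4 genes of chromosome 15. Apobec3, an antiviral cytidine deaminase (chromosome 15, 79891659 to 79915906), was at 175 ± 5.99 CPM in WT and 67.3 ± 11.9 CPM in KO (log2 fold change -1.38, SE 0.26, edgeR adjusted p = 1.00). Its neighbour Cbx7, a Polycomb component whose annotated span overlaps it (79915807 to 79971119), was at 10.6 ± 2.02 and 3.49 ± 1.03 CPM. Gml2 (chromosome 15, 74819071 to 74834871), a gene with a close paralog in Gml, was at 5.93 ± 4.57 and 0.491 ± 0.21 CPM, and the Wnt receptor gene Fzd6, on the same chromosome, at 9.85 ± 3.81 and 2.80 ± 1.06 CPM. Alas2, the erythroid enzyme that starts heme synthesis, had a 25.7-fold difference that rested on 333 CPM in KO replicate 2. KO replicates 1 and 3 were at 13.5 and 19.4 CPM against 3.27 to 5.65 CPM in WT. Trim10, an erythroid gene, Trib3, a stress-induced pseudokinase, and Gda, a guanine deaminase, were likewise highest in KO replicate 2, at 106, 23.5 and 16.2 CPM. The T cell receptor constant segment Tcrg-C1, which has near-identical paralogs, was at 6.10 ± 0.998 and 31.1 ± 26.9 CPM.

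**Figure D2:**
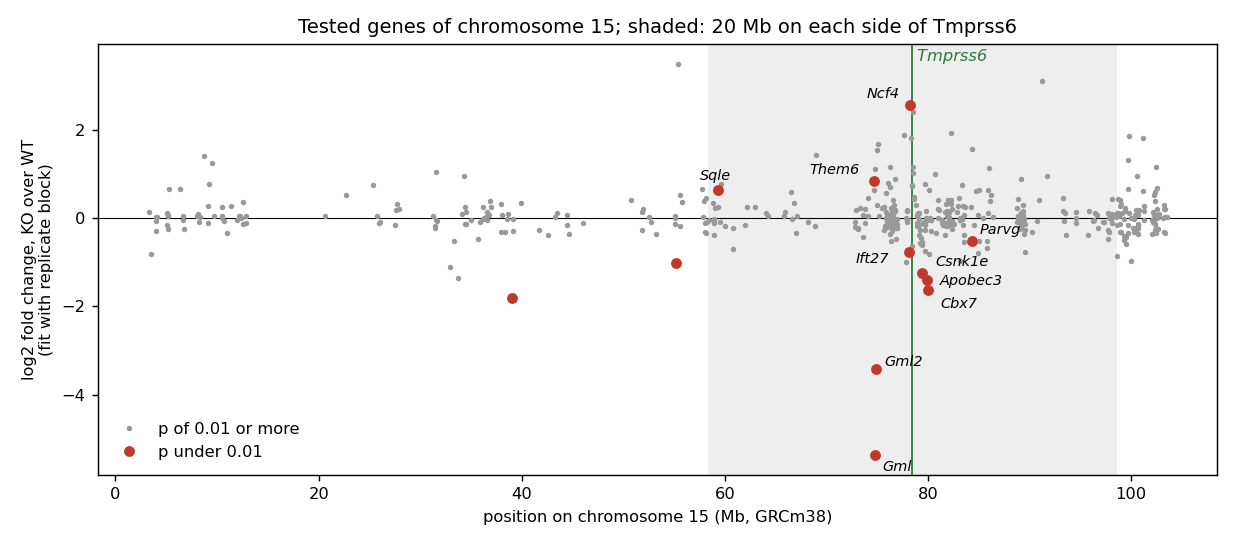
Log2 fold change, KO over WT, of each tested gene along chromosome 15 in the block fit, with genes at p under 0.01 in red and named inside the shaded 20 Mb on each side of Tmprss6. In the shaded stretch 10 of 284 genes are red, among them Apobec3, Cbx7, Gml and Gml2 below 0.

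In the pairs 1 and 3 alone, with the replicate number as a block, 117 of 13572 genes passed the threshold, 35 higher and 82 lower in KO, with 1789 at an unadjusted p under 0.05. This comparison was chosen after the data were seen. The newer quasi-likelihood method of edgeR called 226 genes there, which included all 117. Leaving out KO replicate 2 alone, without a block, gave 0 calls and 146 genes at an unadjusted p under 0.05. Tfrc led the pairs (3.26-fold, log2 fold change 1.70, SE 0.11, adjusted p = 1.70e-06). Hbb-bs and Hba-a1, genes of adult hemoglobin with near-identical paralogs, rose 3.20-fold and 2.47-fold, Alas2 3.82-fold, and Asns, which makes asparagine and is induced by amino acid stress, 1.74-fold. Apobec3, Cbx7, Gml2 and Fzd6 fell by log2 fold changes of -1.41, -1.84, -3.50 and -1.74. Over the alternatives, the adjusted p of Tfrc ranged from 2.23e-18 to 1.00 and that of Apobec3 from 2.24e-09 to 1.00, both lowest in DESeq2 with the block on all 6 libraries, while their log2 fold changes stayed between 1.64 and 2.22 and between -1.50 and -1.25. Markers of other cells were among the 117, named here after their values were seen. Jchain rose (log2 fold change 6.92, the third smallest p), while the eosinophil genes Prg2, Epx and Prg3 (-2.85, -3.55 and -3.51), the neutrophil granule genes Ngp and Ltf (-3.06 and -3.92), the basophil protease gene Mcpt8 (-2.43) and the collagen gene Col1a2 (-1.56) fell. Transcript length was taken throughout as that of the longest annotated GENCODE transcript of a gene. Its median was 4743 nt for the 82 genes that fell, 2037 nt for the 35 that rose and 3008 nt for all tested genes. Pair 2 had the same direction for 34 of the 35 genes that rose and for 27 of the 82 that fell. This is no independent check, as KO replicate 2 held transcripts of other cells, late erythroblasts among them. Its log2 differences from WT replicate 2 were 4.84 for Hbb-bs and 5.85 for Alas2.

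Genes of the erythroid program were mostly higher in KO, but their lists passed only with camera at its preset correlation. Regrouping the libraries in other ways that part all pairs gave 16 to 18 called lists at that setting, against 19 for the real groups. Of 25 early erythroid genes 17 were higher (median log2 fold change 0.46, camera adjusted p = 1.16e-07), but with an estimated correlation the adjusted p was 0.081. The median difference within the pairs 1, 2 and 3 was 0.25, 0.62 and 0.16. Over all genes tested 0 members passed, and adjusted over the list alone 1 did, Tfrc. In the pairs 1 and 3, 17 members were higher and 8 lower. Of these, 5 passed as higher and 0 as lower over all genes, and 9 and 1 when adjusted over the list alone. Among the 5 were Rhag, an ammonia channel subunit of the red cell membrane (log2 fold change 0.66), and Cpox, a heme synthesis enzyme (0.60). The globin and late erythroblast list was higher in 26 of 28 genes (median 1.15, camera adjusted p = 9.79e-21; adjusted p = 0.18 with an estimated correlation), with medians of 0.33, 2.10 and 0.39 in the 3 pairs. Adjusted over the list alone 6 members passed, against 0 over all genes. Without KO replicate 2 it was still higher (camera adjusted p = 6.58e-11; 1.11e-23 to 0.77 over the alternatives). The 21 genes of heme synthesis and transport were higher in 16 (median 0.28, camera adjusted p = 1.61e-06; adjusted p = 0.15 with an estimated correlation). Alas2 and Cpox rose in the pairs 1 and 3, and Fech, which inserts iron into the heme ring, was at 166 to 229 CPM in WT and 273 to 499 in KO, not past the threshold.

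The list of iron uptake, storage and regulation was higher in 17 of 23 genes (camera adjusted p = 0.00051; adjusted p = 0.23 with an estimated correlation), but pair 1 had a median of -0.18 and the call was lost without KO replicate 2 (adjusted p = 0.34) and without a filter on low counts (0.079), in a range of 7.77e-05 to 0.78 over the alternatives. Tfrc alone passed when adjusted over the list alone. Hfe, Trf and the iron exporter gene Slc40a1, which macrophages also express, were highest in KO replicate 2, Slc40a1 at 930 CPM against 117 to 218 CPM in the other libraries. Iron-sulfur cluster assembly showed no shift over the 6 libraries (13 of 28 higher, camera adjusted p = 0.75) but passed as lower without KO replicate 1 (0.0038) and as higher in the pairs 1 and 3 (20 of 28, 0.039; adjusted p = 0.46 there with an estimated correlation), in a range of 0.0038 to 0.98 over the alternatives, with Isca1 and Ciapin1 at log2 fold changes of 0.30 and 0.26, neither past the threshold. The iron- and oxoglutarate-dependent dioxygenases were higher in 16 of 37 (camera adjusted p = 0.98). Among them Egln1, an oxygen sensor, had a log2 fold change of 1.25 (SE 0.48, edgeR adjusted p = 1.00) and was higher in 3 of 3 pairs.

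Of 44 megakaryocyte genes 21 were higher (median -0.011, mean 0.38, camera adjusted p = 0.51), and the 4 of smallest p, Thbs1, Alox12, Tubb1 and Ppbp, were highest in KO replicate 2. Without KO replicate 1 the list passed as higher (camera adjusted p = 0.0078; 0.0078 to 0.98 over the alternatives). Gata1, Gata2, Klf1 and Fli1 had log2 fold changes of -0.049, -0.41, 0.078 and 0.058, and Gata2 was lower in 3 of 3 pairs (-0.38 in the block fit, edgeR adjusted p = 0.995; 0.21 to 1.00 over the alternatives). The 26 lineage transcription factors gave a camera adjusted p of 0.75, with a call as lower without WT replicate 1 (0.039; 0.039 to 1.00 over the alternatives). Stem and multipotent progenitor genes were higher in 10 of 24 (camera adjusted p = 0.44). Sox4, a member, was at 165 ± 14.5 CPM in WT and 106 ± 7.33 in KO. Its difference passed in the pairs 1 and 3 (log2 fold change -0.75, edgeR adjusted p = 0.0039, with 0.0039 to 1.00 over the alternatives). The balance of early erythroid over megakaryocyte genes was 2.86 ± 0.33 log2 units in WT and 3.15 ± 0.57 in KO (SD, n = 3), a difference of 0.30 that lay within the spread (two-sided exact permutation p = 0.5, where 0.1 is the smallest possible). Within pairs it was 0.58, 0.063 and 0.25, and without KO replicate 1 the difference was -0.059.

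**Figure D3:**
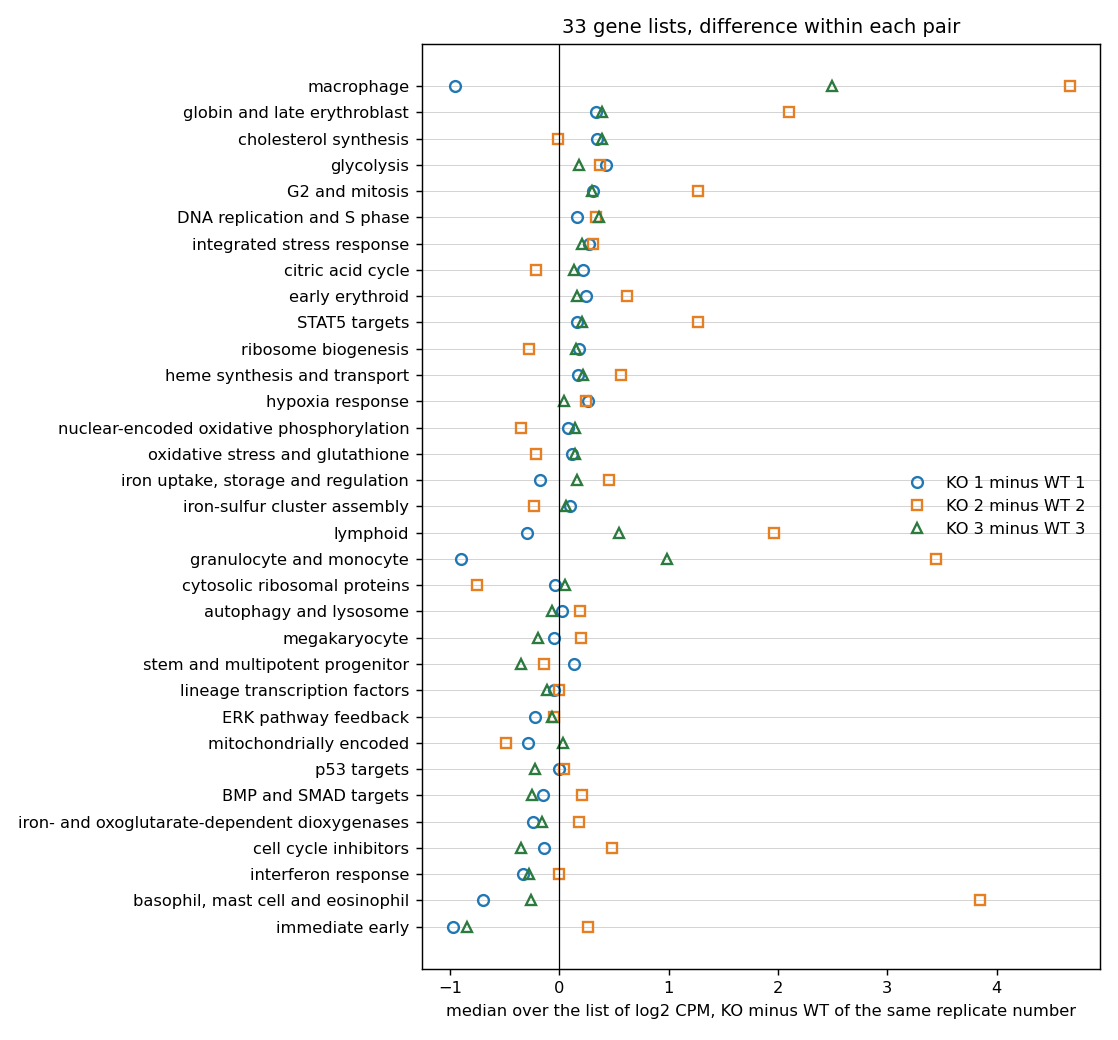
Median over each of 33 gene lists of the log2 CPM difference, KO minus WT of the same replicate number (circles pair 1, squares pair 2, triangles pair 3). The G2 and mitosis, S phase, glycolysis, heme and erythroid lists lie above 0 in all 3 pairs, while lists of other blood cells reach 4.67 in pair 2 and -0.96 in pair 1.

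Most cell cycle genes were higher in KO, but their lists too passed only with camera at its preset correlation. The G2 and mitosis list was higher in 46 of 47 genes (median 0.70, camera adjusted p = 3.76e-29; adjusted p = 0.18 with an estimated correlation), with pair medians of 0.31, 1.26 and 0.30. DNA replication and S phase genes were higher in 41 of 45 (median 0.28, camera adjusted p = 2.85e-10; adjusted p = 0.081 with an estimated correlation), with pair medians of 0.16, 0.33 and 0.36. No member of either list passed edgeR's test over all genes or adjusted over the list alone in the 6 libraries. When only the pairs 1 and 3 were compared, the mitotic kinase gene Aurkb (log2 fold change 0.67), the cyclin gene Ccna2 (0.65), the spindle checkpoint gene Bub1 (0.66), the nucleotide reductase subunit Rrm2 (0.74) and the cyclin gene Ccne1 (0.54) rose. Adjusted over the list alone, 19 G2 and mitosis genes rose and 1 fell there, and 17 S phase genes rose and 0 fell. Both lists passed without KO replicate 2 (camera adjusted p = 6.99e-11 and 2.89e-10), and over the alternatives their adjusted p reached 0.53 and 0.42. Cell cycle inhibitors were higher in 11 of 19 (camera adjusted p = 0.60) and p53 targets in 11 of 28 (camera adjusted p = 0.32). Among the pairs 1 and 3 the inhibitors were lower in 15 of 19 (median -0.32, camera adjusted p = 0.00027; up to 0.98 over the alternatives) and p53 targets in 20 of 28 (0.017; up to 0.94). Their adjusted p there was 0.46 with an estimated correlation.

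The integrated stress response list, genes induced by the transcription factor ATF4, was higher in 25 of 33 (median 0.25, camera adjusted p = 1.62e-05; adjusted p = 0.081 with an estimated correlation), with pair medians of 0.27, 0.31 and 0.20. Asns stood at 132 ± 33.8 CPM in WT and 259 ± 43.7 in KO, Mthfd2 and Cars had log2 fold changes of 0.89 and 0.51, and none of these passed edgeR's test over all genes in the 6 libraries. Asns rose in the pairs 1 and 3, while Ppp1r15a, another member, fell there (named after its values were seen). Glycolysis genes were higher in 22 of 22 (median 0.33, camera adjusted p = 2.57e-06; adjusted p = 0.15 with an estimated correlation), with 0 members past the threshold over all genes and 9 adjusted over the list alone in the pairs 1 and 3. Pgam1 and Slc16a3 had log2 fold changes of 0.53 and 0.80. Hypoxia response genes were higher in 23 of 30 (camera adjusted p = 0.0023; adjusted p = 0.19 with an estimated correlation), a call lost without WT replicate 1 (0.18) or KO replicate 1 (0.090), in a range of 0.0021 to 0.57 over the alternatives. Cholesterol synthesis genes were higher in 22 of 24 (camera adjusted p = 0.00060; adjusted p = 0.18 with an estimated correlation), a call lost without KO replicate 1 (0.23) or KO replicate 3 (0.086), in a range of 3.18e-08 to 0.57 over the alternatives. Sqle, which makes squalene epoxide, rose in the pairs 1 and 3 (log2 fold change 0.76), and pair 2 had a list median of -0.016. The lists of oxidative phosphorylation, citric acid cycle, oxidative stress and glutathione, and autophagy and lysosome gave camera adjusted p of 0.51, 0.59, 0.34 and 0.20. Oxidative phosphorylation passed as higher without WT replicate 1 (7.78e-07) or KO replicate 2 (0.00051) and as lower without WT replicate 3 (4.28e-06) or KO replicate 1 (1.55e-12), with up to 0.98 over the alternatives. The oxidative stress list passed as higher in the pairs 1 and 3 (27 of 33, 0.0015; 0.0015 to 0.91 over the alternatives), with an adjusted p of 0.46 there with an estimated correlation. The citric acid cycle passed as higher without KO replicate 2 (0.0034; 8.86e-06 to 0.98 over the alternatives).

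Immediate early genes are induced by cells within minutes of a stimulus or of handling. As a list they were lower in KO by camera at its preset correlation, with a median above 0 in pair 2. The list was lower in 15 of 23 genes (median -0.31, camera adjusted p = 1.43e-05; adjusted p = 0.50 with an estimated correlation), with pair medians of -0.98, 0.26 and -0.84. The call was lost without WT replicate 1 (0.060) or KO replicate 3 (0.39), in a range of 4.82e-37 to 0.94 over the alternatives. In the pairs 1 and 3, 21 members were lower and 2 higher, and over all genes 9 passed as lower and 0 as higher. Among the 9 were Jun (log2 fold change -1.22, edgeR adjusted p = 1.96e-05, up to 1.00 over the alternatives), Junb (-0.92), Egr1 (-0.86) and Ier2 (-0.68). Jun was at 403 to 646 CPM in WT and 170 to 399 in KO. In pair 2, Jun, Egr1 and Ier2 were also lower (log2 differences of -0.31, -0.40 and -0.46) and Junb was higher (0.15); the difference between pairs was not tested. Interferon response genes were lower in 27 of 35 (camera adjusted p = 0.0097; adjusted p = 0.57 with an estimated correlation), with Oas1a and Xaf1 at log2 fold changes of -0.55 and -0.51. That call was lost without WT replicate 3 (0.77) or KO replicate 1 (0.93), in a range of 0.00010 to 0.94 over the alternatives. Genes induced by STAT5, which acts below the erythropoietin receptor, were higher in 13 of 17 (median 0.70, camera adjusted p = 4.03e-10; adjusted p = 0.18 with an estimated correlation), with pair medians of 0.16, 1.27 and 0.21. Tfrc passed adjusted over the list alone and Socs2 had a log2 fold change of 1.37, not past the threshold. ERK pathway feedback and BMP and SMAD targets gave camera adjusted p of 0.34 and 0.88, and the ERK list passed as lower in the pairs 1 and 3 (10 of 15, 0.019; 0.019 to 0.98 over the alternatives), with an adjusted p of 0.46 there with an estimated correlation. The median, mean and test differed in sign for the megakaryocyte, p53, BMP and SMAD, dioxygenase, lineage factor and ribosome biogenesis lists, none of which passed.

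Lists of other blood cells were higher in KO by camera, but apart from the macrophage list the calls depended on KO replicate 2. The granulocyte and monocyte list was higher in 27 of 28 genes (camera adjusted p = 6.54e-12) and turned lower without KO replicate 2 (adjusted p = 0.00033). The basophil, mast cell and eosinophil list was higher in 17 of 18 (0.00019), lost its call in the block fit (adjusted p = 0.068), with the stricter filter and without WT replicate 3 (0.16), and turned lower without KO replicate 2 (0.0018). The lymphoid list was higher in 24 of 25 (8.25e-08) and lost its call without KO replicate 2 (0.79) and without WT replicate 3 (0.35). The macrophage list was higher in 19 of 20 (1.03e-17) and remained so without KO replicate 2 (0.012), with pair medians of -0.96, 4.67 and 2.49. Over the alternatives the highest adjusted p of these lists was 0.94, 0.95, 0.94 and 0.84. With an estimated correlation the adjusted p of these 4 lists was 0.45, 0.56, 0.50 and 0.22. Ighm, the heavy chain of immunoglobulin M, was at 600 and 562 CPM in KO replicates 2 and 3 against 21.3 to 126 CPM in the other 4 libraries.

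Cytosolic ribosomal protein genes were lower in 79 of 79 (median -0.21, camera adjusted p = 3.03e-06; adjusted p = 0.70 with an estimated correlation). The pair medians were -0.043, -0.76 and 0.052, and the call was lost without KO replicate 2 (adjusted p = 0.94), WT replicate 1 (0.31) or KO replicate 3 (0.39), in a range of 5.70e-24 to 0.98 over the alternatives. In pair 2 genes with longer annotated transcripts tended to be higher in KO. Spearman's rho between transcript length and log2 difference was 0.34, against -0.17 and -0.22 in pairs 1 and 3. Genes are not independent replicates. Rpl3, which lies on chromosome 15, fell in the pairs 1 and 3 (log2 fold change -0.45). Rpl3-ps1, a pseudogene on chromosome X by its name, rose there (1.39), and how reads were divided between them is not known. The 12 mitochondrially encoded genes were lower in 12 (median -0.36, camera adjusted p = 0.023; adjusted p = 0.70 with an estimated correlation), a call lost without WT replicate 1 (0.69), WT replicate 2 (0.98) or KO replicate 3 (0.78), in a range of 2.35e-09 to 0.98 over the alternatives. These transcripts made up 0.226% and 0.227% of the counts in the replicates numbered 3 and 0.650% to 0.936% in the other libraries. Ribosome biogenesis genes were higher in 26 of 51 (camera adjusted p = 0.98) and passed as higher without KO replicate 2 (0.0013) and as lower without KO replicate 3 (0.027; 2.87e-06 to 0.99 over the alternatives). In all, camera placed 15 lists higher and 4 lower, and 0 of the 33 lists passed with an estimated correlation or with fry, whose smallest adjusted p were 0.081 and 0.34. In the pairs 1 and 3 camera placed 17 lists higher and 7 lower, and 0 passed with an estimated correlation (smallest adjusted p = 0.46).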

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

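The block fit of 2 pairs, sex of the mice, the robust prior, the newer quasi-likelihood method DESeq2 with a block, the Tmprss6 settings and the list tests that join a block to fry or an estimated correlation were chosen after the data were seen. The count of 0 genes stayed at 0 under other scalings, filters and thresholds, voom, a minimum fold of 1.5, sex as a covariate, male libraries alone and a replicate block, and without each library in turn (0 to 0). It became 7 with DESeq2 and 26 with DESeq2 and a replicate block. With the replicate block it became 117 in pairs 1 and 3 (226 by the newer method), 99 in pairs 2 and 3, all higher, and 0 in pairs 1 and 2. These fits have fewer samples, and the cause of the differences was not tested. The Tmprss6 difference moved by less than its spread in the 7 settings run.

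The 19 lists that passed became 0 with camera and an estimated correlation, 0 with fry, and 0 with either of these and a replicate block. Between the camera runs only the correlation setting differed, preset at 0.01 or estimated for each list. The estimate was 0.93 for cytosolic ribosomal proteins and 0.47 for G2 and mitosis. It was -0.00023 for the integrated stress response, which lost its call too, so a high estimate does not account for every loss. The cause of the losses with fry was not tested. Other settings gave 17 to 24 lists, without each library 16 to 19, and 18 with a replicate block, which ended the basophil, mast cell and eosinophil call and changed no other call. The KO minus WT difference in the balance of early erythroid over megakaryocyte genes was 0.30. It ran from -0.059 without KO replicate 1 to 0.56 when a library was left out. A replicate block could not change this difference, since every replicate number holds a library of each genotype.

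Over 18 settings, 5 of the 19 lists that passed turned direction, and turns of the other lists were not counted. In the pairs 1 and 3, the granulocyte and monocyte list (adjusted p = 0.22), the basophil, mast cell and eosinophil list (1.84e-11) and the cytosolic ribosomal protein list (0.66) turned. When a library was left out, the adjusted p ran from 2.04e-19 to 0.00092 for granulocytes and monocytes, from 4.05e-19 to 0.79 for lymphoid genes, from 2.36e-16 to 0.16 for basophils, mast cells and eosinophils, from 2.35e-09 to 0.98 for mitochondrially encoded genes and from 5.70e-24 to 0.94 for cytosolic ribosomal proteins, with a turn in each range. The cause was not tested. Of 96 named genes 14 turned, none past the threshold in either direction. In the pairs 1 and 3 the log2 fold changes became -0.31 for Fcgr2b, 0.16 for Gata1, -0.062 for Fli1, -0.18 for Alox12, -0.023 for Tubb1, -0.12 for Slc25a37 and -0.055 for Pmaip1. Itga2b became 0.023 with the stricter filter, 0.019 with a replicate block and 0.017 with voom. Without each library in turn, in fits without pairs, Kit ran from -1.10 to 0.23, Fcgr2b from -0.30 to 1.99, Slamf1 from -0.32 to 0.41, Eng from -0.44 to 0.19, Itga2b from -0.16 to 0.19, Gata1 from -0.17 to 0.13, Gata2 from -0.92 to 0.10, Klf1 from -0.046 to 0.23, Fli1 from -0.20 to 0.38, Slc25a37 from -0.10 to 2.15 and Mgst1 from -0.032 to 3.45. The other named genes kept their direction in the 13 to 15 settings run for each. Depth limits Tmprss6, at 0 to 5 counts in each library.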

Other observations

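Several gene groups that stayed short of the threshold over all 6 libraries moved together in the pairs 1 and 3, a comparison chosen after the data were seen. Nuclear-encoded oxidative phosphorylation genes were higher in 65 of 76 (median log2 fold change 0.12, camera adjusted p = 4.53e-07), citric acid cycle genes in 22 of 23 (0.17, 8.86e-06) and ribosome biogenesis genes in 43 of 51 (0.16, 2.87e-06). Pair 2 had medians of -0.35, -0.22 and -0.28 for these lists. Iron- and oxoglutarate-dependent dioxygenases were lower in 25 of 37 (camera adjusted p = 0.00039), and adjusted over the list alone 8 fell and 1 rose, while over all genes 2 fell, the histone demethylase genes Kdm5b and Kdm6a (log2 fold changes of -0.60 and -0.75, named after their values were seen). With an estimated correlation each of these lists had an adjusted p of 0.46. Genes with long annotated transcripts tended to be lower in KO in the pairs 1 and 3. The rank correlation across genes of transcript length and log2 difference was -0.17 in pair 1, 0.34 in pair 2 and -0.22 in pair 3. Genes are not independent replicates. The genes that passed as lower in the pairs 1 and 3 had longer annotated transcripts (median 4743 nt) than those that passed as higher (2037 nt).

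The tests below that were chosen only after their result was seen are those on the placement of genes of low p, on the stretch from 1 to 20 Mb from Tmprss6, on the lists of other cells in KO replicate 2, on the genes called around Tmprss6 and on Tfrc against Hbb-bs. The 6 libraries allow only 10 splits, too few to exclude chance at 1 in 20. The real split called 0 genes, and 10 of the 10 splits called as many. The highest other count was 1993, for WT 1, WT 2 and KO 1 against WT 3, KO 2 and KO 3, which points to a structure of the samples apart from genotype. Of the 4 splits that part all 3 pairs, each called 0 genes. For lists, the real split called 19, as did 1 other (2 of 10), and the other splits that part all pairs called 16 to 18. In the pairs 1 and 3 the real labels called 117 genes and crossing the labels of 1 pair called 13 (1 of 2 arrangements as large), again too few to exclude chance.

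Genes of low p, named after their values were seen, gathered around Tmprss6. Within 20 Mb on each side, 10 of 284 tested genes had p under 0.01 in the block fit against 56 of 13169 elsewhere (odds ratio 8.54, 95% interval 3.84 to 17.1). This interval and those below take neighbouring genes as independent. Random runs of as many neighbouring genes held as many in 177 of 10000 draws, a share of 0.0178. Runs on any other chromosome held at most 5, so the 177 lay on chromosome 15 and overlapped the stretch itself. The share is therefore not the chance of such a gathering elsewhere. Cells of other types in KO replicate 2 do not account for all of the gathering, since the odds ratio without the libraries numbered 2 was 2.26 (1.47 to 3.35). A contribution of that library is not excluded, as the ratio was lower than with it. The ratios cannot be set side by side, because elsewhere 4.82% of genes had p under 0.01 without those libraries and 0.425% with them. The other libraries hold transcripts of other cells too. A candidate explanation is passenger DNA of another strain carried along with the targeted allele: from 1 to 20 Mb the odds ratio was 6.83 (2.60 to 15.2), with 2 genes higher and 5 lower, although in the pairs 1 and 3 it was 1.93 (1.18 to 3.02). The strain of the mice is not in the labels and no variants were examined, so an effect of Tmprss6 loss on these genes stays open.

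KO replicate 2 may hold cells of other types. The lowest of the 5 median differences of its lists of other cells from the other 5 libraries was 2.17 log2 units, and 22 of 28 globin and late erythroblast genes, but only 4 to 6 genes of each other list, reached 5 CPM in all other libraries. The sort should remove lineage-positive and Fc gamma receptor-positive cells, and how these cells or their RNA entered is open. A library of WT mice under a KO label was tested on 28 genes around Tmprss6 with p under 0.01 in the pairs 1 and 3. KO replicate 2 lay on the KO side in 57.1% (95% exact interval 37.2 to 75.5), which does not decide it, whereas WT replicate 2 lay on the WT side in 27. In that fit 4.82% of genes elsewhere also had p under 0.01, against 10.2% around Tmprss6. Some of the 28 genes may therefore be unrelated to the targeted allele, which weakens the test. Of the 11 genes around Tmprss6 past the threshold there, KO replicate 2 lay on the KO side in 9, with Apobec3 at 69.8 CPM against 54.3 and 77.6 CPM in the other KO libraries and 168 to 180 CPM in WT.

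Tfrc was higher in every KO library. Late erythroblasts among the sorted cells stay open: the Tfrc excess over WT per unit of Hbb-bs excess in KO replicates 1 and 3 was at least 5.97 times that in replicate 2, but this assumes the profile of that library, and Hbb-bs and Alas2 rose 3.20-fold and 3.82-fold in the pairs 1 and 3. Cells further along the early erythroid program remain a candidate explanation, as 58.3% of the 24 other early erythroid genes (14) were higher in KO in both of the pairs 1 and 3, where chance gives 25% (one-sided exact binomial p = 0.00052) and 28.0% of all genes were (p = 0.0018 against that share, exact). These p take the genes as independent, and the whole list in these pairs had an adjusted p of 0.46 by camera with an estimated correlation. Joint stabilisation of transcripts with a 3' iron-responsive element, which protects Tfrc mRNA when iron is scarce, predicted higher Slc11a2, Cdc14a and Cdc42bpa in both pairs. This was not met. The log2 differences in pairs 1 and 3 were 0.096 and 0.14 for Slc11a2, -0.67 and -0.62 for Cdc14a and -0.31 and 0.15 for Cdc42bpa. Their median log2 fold change of -0.068 did not lie below 0 by more than their SD, the limit set for the opposite reading, so these genes could not decide it. Iron deficiency, which the series title names and which was not measured here, stays open.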
